A study of Mus musculus with 4 samples.

How the data were processed

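RNA was sequenced from Pdgfrb-GFP positive cells sorted from lungs of mice on postnatal day 7. The labels give 2 wild-type (WT) and 2 Dnmt1 conditional knockout (CKO) replicates. The authors deposited raw read counts per gene in a table of the whole series. Per the submitters' processing notes, which name the tools without their order, FastQC 0.11.8, cutadapt 2.5, Trimmomatic 0.36, STAR and edgeR 3.28.1 were used with genome build GRCm38.p6. The counting tool and its use of strand are not given in the sources used here, so that reads of overlapping or antisense genes cannot be told apart. The table lists only genes with at least 1 read in some library. The authors also deposited a log2 fold change of mutant against control, a p-value and an adjusted p-value per gene, per the file headers, and these are quoted only where named as theirs. A gene length in bases is given as well. The table holds 4 further columns of per-sample values that were not used. The count columns are named Control or Mutant, read here as the WT and CKO of the labels. They open with a number, shared by WT B, CKO A and CKO B but not by WT A, and give no replicate. Libraries were therefore given letters in column order that carry no pairing.

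Gene coordinates and types came from GENCODE mouse release M21 on GRCm38, matched by Ensembl identifier for 31171 of 31247 genes (99.8%). Depth ranged from 23071657 to 26420648 counted reads, and 1 read corresponded to 0.0377 to 0.0439 CPM, the read count scaled to a common library size. Each library had between 9.76% and 11.6% of its reads on its top 10 genes and between 2.06% and 2.63% on mitochondrial genes.

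The comparison of CKO with WT was run in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its default minimum count of 10, libraries were scaled by TMM, and glmQLFit and glmQLFTest were used with robust estimation. Adjusted p-values are Benjamini-Hochberg values over the 15210 tested genes, with a threshold of 0.05, and the biological coefficient of variation was 0.160. Standard errors were taken as the log2 change divided by the square root of the F statistic. The same adjusted values were also computed over each gene list alone. A gene with 0 WT reads is given a lower bound against a floor of 3 reads over the WT group, and a gene with 1 to 3 WT reads is given a ratio with an exact 95% interval. Such intervals and floors cover counting error only, and PCR copies are not independent molecules. Fitted changes of such genes depend on the prior count.

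Before the data were examined, 29 gene lists were fixed, covering germline genes, DNA methylation machinery, imprinted genes, interferon-stimulated genes, stress, p53, cell cycle, matrix, signalling and cell type markers, and sex-linked genes. Lists were tested with camera at a preset correlation of 0.01 (limma 3.58.1), two-sided and adjusted over the lists, and again with an estimated correlation and with fry. A correlation estimated from 4 libraries is uncertain, so a list not called with it is not shown to be unchanged. The rule for named genes was also fixed then. It takes Dnmt1, Pdgfrb, the sex-linked genes, up to 4 tested members per list with the lowest p, and the 12 largest rises and 12 largest falls among called genes with a mean log2 CPM of at least 1 and groups that do not overlap, leaving out predicted or unnamed genes and pseudogenes. Members named because a count was 5 or fewer, and the genes Plk2, Igfbp5, Impact, Inpp5f, Tuba3a, Tuba3b, Dmc1 and H19, Cdh19 and Gm10800, were chosen after their values were seen.

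The tests were tried on simulated counts for 15210 genes with the means and depths of this comparison. In edgeR 60 of 100 genes changed 2-fold and 81 of 100 genes changed 4-fold were recovered, and 23 of 15010 unchanged genes were called. Those 23 made up a larger share of the simulated calls than the threshold of 0.05. The threshold therefore did not hold the share of false calls in this simulation. Camera called 3 of 100 unchanged lists at an unadjusted p under 0.05. The simulated genes were drawn independently, so this error rate need not hold for the real lists. Their estimated correlations ran from -0.0563 (pericyte markers) to 0.920 (chondrocyte markers). Other settings fixed in advance were DESeq2 1.42.0, limma-voom, RLE size factors, library size alone, no filter on low counts, a mean CPM of at least 1, an adjusted p under 0.01, glmTreat against a 1.5-fold change, and leaving out each library in turn. Removal of the trend with gene length, robust estimation switched off and autosomal genes alone were added after the data had been seen, as were all settings for the direction of calls by expression level.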

Results

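The transcriptome of lung mesenchymal cells labelled as a conditional knockout of Dnmt1, the maintenance DNA methyltransferase, was compared with that of wild-type cells by RNA sequencing. Cells carrying a Pdgfrb-GFP reporter, which the labels call myofibroblasts, were sorted from mouse lungs on postnatal day 7. The labels give 2 wild-type (WT) and 2 Dnmt1 conditional knockout (CKO) replicates, and the sample titles do not give the number of animals in each. The 4 libraries are named here by genotype and by a letter in column order. WT A held 23071657 counted reads, WT B 25709717, CKO A 26420648 and CKO B 23581186. Reads were found for 31247 genes in at least 1 library. WT B stood apart in breadth, with reads on 27643 genes against 21883 in WT A, 22237 in CKO A and 22532 in CKO B. Pearson correlations of log2 CPM across genes were 0.985 between the WT libraries, 0.982 between the CKO libraries and 0.941 to 0.954 between genotypes, with genes not being independent replicates. Replicates of a genotype differed by more than sampling noise, with a chi-square per degree of freedom of 20.4 for WT and 36.0 for CKO, and were counted as separate samples. The labels do not say whether animals shared a litter, so p-values measure the spread between these libraries. The names of the count columns open with a number that WT B, CKO A and CKO B share and WT A does not, and what it marks is not stated in the sources used here. The comparison within the shared number is the one without WT A, with 1 WT library.

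Dnmt1 itself, the targeted gene (ENSMUSG00000004099, chromosome 9, 20907209 to 20959888, GRCm38), was lower in both CKO libraries than in either WT library. Its level was 144 CPM in WT A, 115 in WT B, 78.2 in CKO A and 29.5 in CKO B, so that CKO A kept 60.3% and CKO B 22.8% of the WT mean. The log2 change was -1.27 ± 0.57 (SE, n = 2 per genotype), and edgeR's quasi-likelihood test did not call it (adjusted p = 0.31). Without CKO A the change was -2.11 (adjusted p = 3.8e-05) and without CKO B it was -0.72 (adjusted p = 0.040). The authors' deposited table gives a log2 fold change of -1.23 and an adjusted p of 0.029 for Dnmt1. Counts were summed over the whole gene, so reads from exons outside a deletion are included. Pdgfrb, the gene whose reporter was sorted on (chromosome 18, 61045150 to 61085061), stood at 492 ± 20.6 CPM in WT and 345 ± 40.0 in CKO (SD, n = 2), a log2 difference of -0.51 that did not pass (edgeR adjusted p = 0.0546).

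Sex-linked transcripts differed within the CKO genotype. CKO A held 2494 reads of Ddx3y, 989 of Eif2s3y, 562 of Kdm5d and 399 of Uty, all Y-linked, while the other 3 libraries held 0 reads of each. Xist, the RNA that silences an X chromosome in female cells, was at 849 CPM in WT A, 671 in WT B, 164 in CKO A and 1081 in CKO B. Its antisense partner Tsix had between 0 and 4 reads per library. The Y-linked genes and Tsix were too low in most libraries to be tested in edgeR, and Xist, the tested member of its list, did not pass (log2 difference -0.29 ± 1.18, edgeR adjusted p = 0.916). DESeq2 called 4 members of the sex-linked list higher and 0 lower, and edgeR without CKO B 4 higher and 1 lower. Camera did not call that list, of which Xist alone was tested (adjusted p = 0.720). Without CKO B the Y-linked genes entered the test and the list held 5 tested members. That fit sets CKO A, with Y-linked reads, against WT libraries with 0, so its calls of Y-linked genes follow from that difference.

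**Figure D1:**
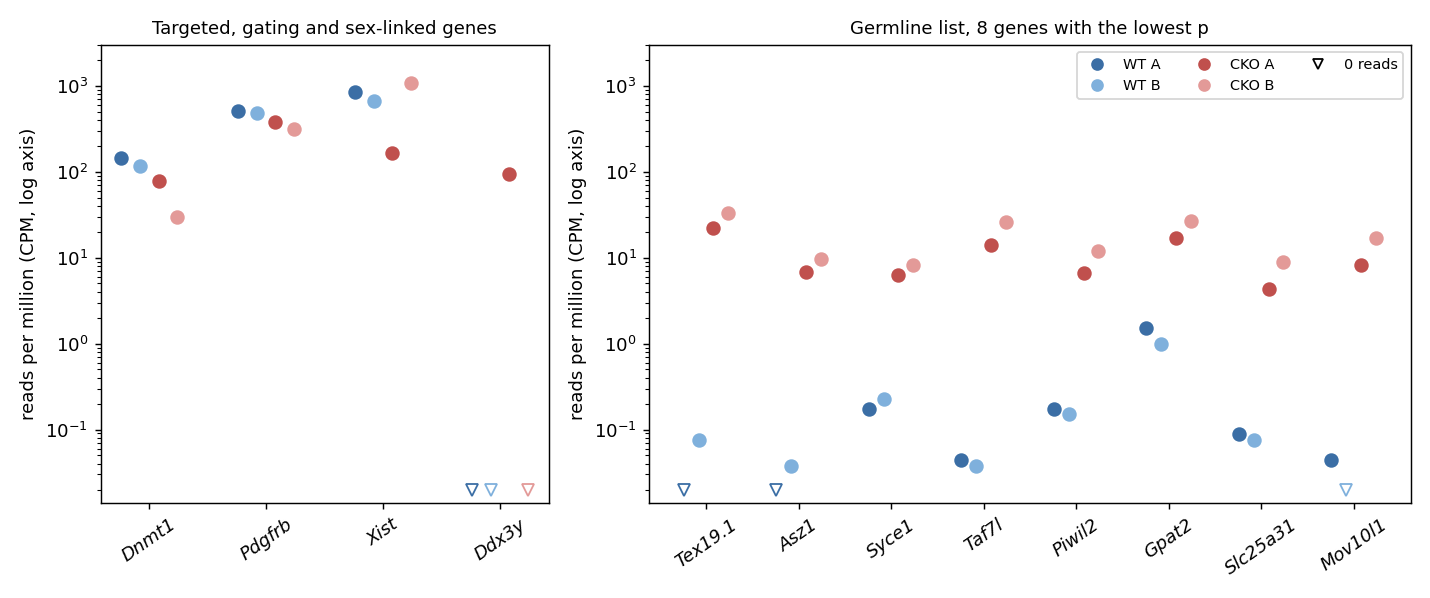
Normalised read counts (CPM, log axis) in each of the 4 libraries, 1 point per library, for Dnmt1, Pdgfrb, Xist and Ddx3y (left) and for the 8 germline genes with the lowest p (right). Open triangles mark 0 reads. Each germline gene was higher in both CKO libraries than in either WT library, and Ddx3y had reads in CKO A alone.

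The libraries labelled CKO showed more rises than falls among called genes. Of 15210 genes tested, 1157 changed, 738 of them higher (63.8%) and 419 lower in CKO (edgeR, adjusted p under 0.05). The rises reached far greater sizes, with 237 genes at least 8-fold higher against 10 at least 8-fold lower. The groups did not overlap for any of the 1157 called genes, and for 57.1% of all tested genes, where chance gives 33.3%. The count depended on the libraries used, and was 603 without WT A (the comparison within the shared column number), 339 without WT B, 1842 without CKO A and 1055 without CKO B. None of these fits called a gene in the opposite direction to the fit of all 4 libraries. The authors' deposited table lists 1345 genes at an adjusted p under 0.05, 950 higher and 395 lower, and 1041 genes were called in both, all with the same sign.

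In the quartile of tested genes with the lowest mean expression 216 were higher and 55 lower, whereas in the quartile with the highest expression 128 were higher and 144 lower. The odds ratio was 4.41 (95% interval 2.97 to 6.59, Fisher's exact test, two-sided, p = 2.1e-15). Without WT A the odds ratio was 0.442. Genes were filtered and quartiles formed anew in that fit, with 16584 genes tested. Its lowest quartile therefore need not hold the same genes, and no gene called in both fits changed direction. WT B, the WT library left in that fit and the one that shares its column number with the CKO libraries, was the library with reads on the most genes.

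**Figure D2:**
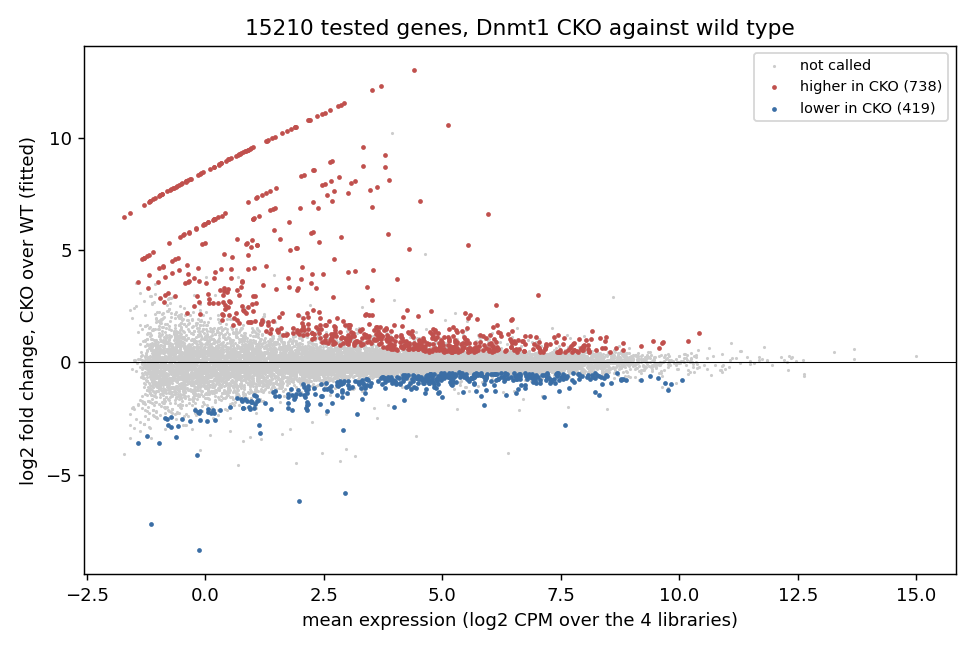
Fitted log2 fold change of CKO over WT against mean expression (log2 CPM over the 4 libraries) for the 15210 tested genes, 1 point per gene. Of the called genes, 738 lie above and 419 below the line of no change. The straight bands at the upper left are genes with 0 or very few WT reads, whose fitted change depends on the prior count.

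Most of the tested germline genes, a list of genes that promoter methylation keeps silent in somatic tissue, were higher in CKO. Of 34 members tested, 22 were higher and 0 lower in CKO, and 29 were higher when adjusted over the list alone. The list held 56 genes, and a member near 0 reads in WT passed the filter only through its CKO reads. The tested members therefore lean to rises. With no filter on low counts 32 of 52 were higher and 0 lower, with a median log2 change of 4.26. Tex19.1, which restrains transposons in germ cells, had 2 reads in the WT libraries together and 1342 in the CKO libraries, a ratio of 669 (95% counting interval 185 to 5528, edgeR adjusted p = 0.000745). Asz1, a piRNA pathway gene, had 1 read in WT and 405 in CKO, a ratio of 404 (72.0 to 15980). Syce1, a component of the synaptonemal complex, was at 0.201 ± 0.0359 CPM in WT and 7.20 ± 1.41 in CKO (SD, n = 2), 34.7-fold higher. Taf7l, a germ cell TFIID subunit, had 2 reads against 968. Members that did not pass were Tuba3a and Tuba3b, near-identical tubulin genes that can share reads, which had 1 and 0 reads in WT but 1460 and 2021 in CKO with a wide spread between the CKO libraries, and others such as Dmc1 (log2 difference -0.47). The list median was 5.96 on the log2 scale, or 5.46 with members at 0 WT reads set at their lower bound. Camera with its preset correlation called the list (adjusted p = 2.76e-22), and with an estimated correlation it did not (adjusted p = 0.437). The count of higher members was 18 without WT A, 15 without WT B, 28 without CKO A and 22 without CKO B.

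The 12 largest rises under the naming rule were mostly of genes with no reads in WT. Sohlh2, a germ cell transcription factor (chromosome 3, 55182028 to 55209957), had 0 reads in WT and 1269 in CKO, at least 422-fold higher against a floor of 3 reads over the WT libraries (edgeR adjusted p = 0.00922). Serpinb1c, of a serine protease inhibitor family with close paralogs (chromosome 13, 32881434 to 32898211), had 0 and 1110 reads and was at least 369-fold higher. Dazl, a germ cell RNA-binding protein gene (chromosome 17, 50279395 to 50293636), had 2 and 3366 reads, a ratio of 1677. Tex101, a germ cell glycoprotein gene, was at least 116-fold higher. X-linked members were the plasmacytoma transcript Pet2 (at least 230-fold), the tumour antigen gene Trap1a (at least 198-fold) and the homeobox gene Rhox2d (at least 105-fold), the last from a cluster of near-identical copies. Rpl39l, a ribosomal protein paralog, was at least 223-fold higher and Rnf183, a ubiquitin ligase gene, at least 163-fold. Pkd1l2, of the polycystin family, was at least 145-fold higher, the receptor gene Qrfprl at least 116-fold and the hepcidin paralog Hamp2 at least 82.7-fold. All 12 were higher in both CKO libraries than in either WT library. Dazl and Pet2 lost their calls without WT A, and Dazl, Pet2, Qrfprl and Tex101 without WT B.

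The 12 largest falls were smaller than the 12 largest rises. Eno1b, an enolase gene close in sequence to Eno1 (chromosome 18, 48045335 to 48048412), stood at 7.58 ± 0.525 CPM in WT (SD, n = 2), had 372 reads in WT and 5 in CKO, and was 71.5-fold lower (edgeR adjusted p = 0.000671). Rasgrf1, an imprinted Ras exchange factor gene (chromosome 9, 89909908 to 90026977), was 8.78-fold lower and the potassium channel gene Kcna6 7.97-fold lower. Ccdc3 fell from the highest starting level of the group, 334 ± 22.9 to 48.7 ± 21.4 CPM, 6.85-fold lower. Lama1, encoding a laminin chain of basement membranes, was 3.98-fold lower, and Adam33, a membrane metalloprotease gene, was 3.76-fold lower. The homologous recombination gene Xrcc3 was 3.19-fold lower, from 27.9 ± 3.44 to 8.76 ± 1.83 CPM. Tafa1 was 4.51-fold, Nxnl2 4.14-fold, Cpne7 3.74-fold, Slc25a27 3.50-fold and Gap43 3.37-fold lower. Without WT A the calls of Ccdc3, Gap43 and Nxnl2 were lost, without WT B those of Ccdc3, Cpne7, Gap43, Rasgrf1 and Tafa1, and that of Adam33 without CKO A and again without CKO B.

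Some interferon-stimulated genes and some immune cell markers were higher in CKO. Of 42 interferon-stimulated genes, 9 were higher and 0 lower, and 17 were higher when adjusted over the list alone. Isg15, a ubiquitin-like modifier, was at 0.493 ± 0.263 CPM in WT and 12.5 ± 5.03 in CKO (SD, n = 2), 24.7-fold higher (edgeR adjusted p = 0.00401). The antiviral genes Oasl1 and Ddx60 were 17.9-fold and 7.73-fold higher, and Bst2, which tethers virions, was 2.87-fold higher. Of 18 immune cell markers 6 were higher and 0 lower, and 11 were higher when adjusted over the list alone. Cd74 was at 6.06 ± 1.99 CPM in WT and 18.0 ± 2.93 in CKO, Fcer1g was 3.46-fold, Cd14 3.24-fold and Laptm5 2.40-fold higher. Camera called both lists with its preset correlation (adjusted p = 9.48e-10 and 9.41e-06) and neither with an estimated correlation (adjusted p = 0.437 and 0.660). The count of interferon-stimulated genes was 5 without WT B and 7, with 1 lower, without CKO B, and that of immune markers was 1 without WT A and 2 without WT B.

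Many genes of the unfolded protein and integrated stress responses were higher in CKO. Of 32 members 15 were higher and 0 lower, and 22 were higher when adjusted over the list alone. Slc3a2, a subunit of amino acid transporters, was at 103 ± 2.03 CPM in WT and 226 ± 26.5 in CKO (SD, n = 2), 2.20-fold higher (edgeR adjusted p = 0.00369). Phgdh, an enzyme of serine synthesis, was 2.21-fold higher, Sesn2, a stress-induced regulator of mTORC1, 2.03-fold higher and the transcription factor gene Atf5 1.93-fold higher. Camera gave an adjusted p of 9.48e-10 with its preset correlation and an adjusted p of 0.437 with an estimated correlation. The count was 7 without WT A and 7 without WT B. Dissociation stress genes, which cell isolation can induce, moved the same way, with 5 of 24 higher (Ier3, Klf4, Klf2, Atf3 and Nr4a1), 0 lower and 14 higher when adjusted over the list alone. Ier3 was 2.03-fold and Klf4 1.79-fold higher. That list was called with the preset correlation (adjusted p = 9.94e-05) and not with an estimated correlation (adjusted p = 0.739), and its count was 3 without WT A, 3 without WT B, 13 without CKO A and 3 without CKO B.

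Some p53 targets and some Cdk inhibitor and senescence genes were higher in CKO. Of 35 p53 targets 9 were higher and 1, the kinase gene Plk2, was lower, and 17 were higher and 1 lower when adjusted over the list alone. Cdkn1a, which encodes the Cdk inhibitor p21, was at 36.8 ± 3.32 CPM in WT and 141 ± 28.5 in CKO (SD, n = 2), 3.84-fold higher (edgeR adjusted p = 0.00177). Gdf15, a stress-induced cytokine gene, was 7.47-fold higher and Ddit4, an inhibitor of mTORC1, 2.56-fold higher. Of 24 Cdk inhibitor and senescence genes 7 were higher and 1, Igfbp5, was lower, and adjusted over the list alone 10 were higher and 2 lower. Igfbp7 was 2.61-fold, the metalloprotease inhibitor gene Timp1 2.27-fold and the chemokine gene Cxcl2 6.29-fold higher. Cdkn1a belongs to both lists, and Sesn2 to the p53 and stress response lists. Camera called both with the preset correlation (adjusted p = 1.57e-05 and 0.000769) and neither with an estimated correlation (adjusted p = 0.437 for each). Without WT A and again without WT B neither list had a lower member, and without CKO A 2 Cdk inhibitor and senescence genes were lower.

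Of 40 S phase genes 2 were lower, E2f8 (1.57-fold, edgeR adjusted p = 0.0438) and Tk1 (1.47-fold), and 0 when adjusted over the list alone. No G2/M gene of 40 passed in edgeR, over all genes or adjusted over the list alone, while 13 were lower and 0 higher at an unadjusted p under 0.05. DESeq2 called 0 S phase genes and 1 G2/M gene, lower in CKO, and limma-voom called 0 of either list. Mki67, a marker of cycling cells, stood at 313 ± 7.40 CPM in WT and 234 ± 22.6 in CKO (SD, n = 2, edgeR adjusted p = 0.0744). The log2 changes of 36 of the 40 G2/M genes and 32 of the 40 S phase genes lay below 0, with medians of -0.23 and -0.17. The preset correlation called both lists lower (adjusted p = 0.000904 and 0.0418), an estimated correlation neither (adjusted p = 0.739 and 0.923). Without WT A the S phase list had an adjusted p of 0.960, without CKO B of 0.339, with no filter on low counts of 0.350, in DESeq2 of 0.0520 and with autosomal genes alone just over 0.05, and 0 of its genes were called without WT A or without WT B and 1 without CKO B. In the G2/M list 1 gene was lower without CKO A and 1 without CKO B.

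Few contractile and matrix genes passed in edgeR. Of 34 contractile and myofibroblast genes 3 were higher, Actc1 (2.69-fold, edgeR adjusted p = 0.00644), Nrp1 (1.66-fold) and Cnn1 (1.47-fold), 0 were lower, and adjusted over the list alone 4 were higher and 2 lower. Pdgfra, a receptor of alveolar myofibroblasts, stood at 554 ± 60.3 CPM in WT and 365 ± 58.1 in CKO (SD, n = 2) and did not pass (edgeR adjusted p = 0.0526). Camera did not call the list (adjusted p = 0.843). Without WT B 1 member was higher, without CKO A 6 were higher and 6 lower, and DESeq2 called 3 higher and 4 lower. Of 45 elastic fibre and collagen genes 2 were higher, Postn (801 ± 38.3 CPM in WT and 1533 ± 385 in CKO, 1.91-fold) and Fbln2 (1.89-fold), 0 were lower, and 8 were higher when adjusted over the list alone. The matrix list was called with the preset correlation (adjusted p = 0.00301) but not with an estimated correlation (adjusted p = 0.878). It also lost that call without WT B (adjusted p = 0.238) and without CKO B (adjusted p = 0.0665), and its higher members numbered 0 without WT A, 0 without WT B (where 1 was lower), 16 without CKO A and 11 in DESeq2 (where 1 was lower).

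Some markers of other fibroblast subtypes were higher in CKO. Of 14 adventitial fibroblast markers 5 were higher (Pi16, Igfbp6, Serpinf1, Dpt and Clec3b) and 0 lower, and 7 were higher when adjusted over the list alone. Pi16 was 2.22-fold, Igfbp6 2.18-fold and Serpinf1 2.60-fold higher (edgeR adjusted p = 0.00534, 0.00811 and 0.0231). Of 19 alveolar and lipofibroblast markers 4 were higher, Cxcl14 (2.19-fold), Fgf10 (2.19-fold), Ces1d (1.93-fold) and Col13a1 (2.27-fold), 0 were lower, and 6 were higher when adjusted over the list alone. The preset correlation called both lists (adjusted p = 0.000159 and 5.45e-06), an estimated correlation neither (adjusted p = 0.437 and 0.577). Adventitial calls numbered 2 without WT A, 2 without WT B and 10 without CKO A, and lipofibroblast calls 1, 1 and 12. Of 15 pericyte markers, Gucy1a1 was lower (1.62-fold) and Ndufa4l2 higher (2.10-fold), with the same counts adjusted over the list alone. Camera did not call the pericyte list (adjusted p = 0.507). Pericyte calls numbered 0 without WT A and 0 without WT B, 4 higher and 2 lower without CKO A, and 0 higher and 1 lower without CKO B.

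Among 32 transcription factors of lung mesenchyme 5 were lower, Foxp1 (1.57-fold, edgeR adjusted p = 0.0149), Tshz2 (1.72-fold), Tbx2 (1.53-fold), Nfia (1.52-fold) and Zeb2, and 0 were higher. Adjusted over the list alone, 9 were lower and 3 higher, and camera did not call the list (adjusted p = 0.586). The lower members numbered 1 without WT A, 2 without WT B and 2 without CKO B. Calls went both ways without CKO A (4 higher and 4 lower), without WT A (1 and 1) and in DESeq2 (2 and 7). Of 16 Hox genes 3 were higher, Hoxb8 (2.01-fold, from 15.0 ± 2.04 to 30.1 ± 0.282 CPM, SD, n = 2), Hoxb9 (12.1-fold) and Hoxc4 (3 reads in WT and 56 in CKO, a ratio of 18.6 with a counting interval of 6.05 to 92.9), and 0 were lower. Adjusted over the list alone, 4 Hox genes were higher and 2 lower, and camera did not call them (adjusted p = 0.777), except without WT A, where they were called higher (adjusted p = 0.0342). Median and mean log2 change differed in sign for the Hox genes (-0.13 and 0.43). No Hox gene was called without WT B, and 1 was higher and 1 lower without CKO B.

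Genes of the TGF-beta and BMP, Wnt, and FGF and PDGF lists changed in both directions. In the TGF-beta and BMP list 3 of 39 were higher and 3 lower, among them Id1 (2.00-fold higher, edgeR adjusted p = 0.00369), a BMP target, Bmp5 (1.85-fold higher), Tgfb2 (1.95-fold lower, from 437 ± 12.4 to 224 ± 12.8 CPM, SD, n = 2) and Bmp2 (1.95-fold lower). In the Wnt list 2 of 42 were higher, Wnt6 (4.31-fold) and the secreted inhibitor gene Wif1 (3.17-fold), and 2 lower, Wnt5a (1.72-fold) and Wnt9a (1.57-fold). In the FGF and PDGF list 2 of 24 were higher, Fgf10 and Pdgfa (1.53-fold), and 2 lower, Spry1 (1.65-fold) and Etv1 (1.71-fold), both targets of FGF signalling. Of 16 Hedgehog genes none passed in edgeR over all genes, and 0 were higher and 2 lower when adjusted over the list alone. At an unadjusted p under 0.05 there were 2 higher and 4 lower Hedgehog genes, and DESeq2 called 1 higher and 2 lower where limma-voom called 0. Adjusted over the list alone, the TGF-beta and BMP list held 4 higher and 6 lower, the Wnt list 4 and 3, and the FGF and PDGF list 3 and 6. With all libraries camera called none of these lists (adjusted p = 0.507 for TGF-beta and BMP, 0.507 for Wnt, 0.998 for FGF and PDGF and 0.586 for Hedgehog), and the FGF and PDGF list had a median log2 change of -0.04 but a mean of 0.06. Wnt5a lost its call without WT A, Wif1 and Spry1 without WT B, and Wnt9a, Fgf10 and Pdgfa without WT A and again without WT B, and Pdgfa also without CKO B. The Wnt list was called higher without WT A (camera adjusted p = 0.0467) and with no filter on low counts (adjusted p = 0.0403). Without CKO A the counts of higher and lower genes were 5 and 5 for TGF-beta and BMP, 8 and 4 for Wnt, 6 and 5 for FGF and PDGF and 4 and 1 for Hedgehog. The Wnt list had 2 and 0 without WT A and 1 and 1 without WT B, the FGF and PDGF list 0 and 2, 0 and 1, and 1 and 2 without WT A, WT B and CKO B in turn, and the Hedgehog list 0 and 1 without CKO B.

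Imprinted genes moved both ways. Of 48 tested 2 were higher, Herc3 (4.58-fold, edgeR adjusted p = 0.0120) and Impact, and 4 lower, Ppp1r9a (2.03-fold, from 91.7 ± 4.99 to 45.2 ± 0.0466 CPM, SD, n = 2), the antisense RNA gene Kcnq1ot1 (2.92-fold), Rasgrf1 and Inpp5f. Adjusted over the list alone 6 were higher and 7 lower, and camera did not call the list (adjusted p = 0.720). Kcnq1ot1 overlaps Kcnq1 on the other strand, and strand use in the counting is not given in the sources used here. Kcnq1ot1 lost its call without CKO A and again without CKO B, and Rasgrf1 without WT B. Imprinted genes called higher and lower numbered 6 and 5 without CKO A, 1 and 6 without CKO B, 3 and 2 without WT B and 5 and 5 in DESeq2. Of 25 genes of the DNA methylation machinery Zfp57, which protects methylation at imprinted loci, was lower (1.84-fold, edgeR adjusted p = 0.00778), Gadd45g (1.41-fold) and Gadd45b (1.48-fold) were higher, and adjusted over the list alone 3 were higher and 2 lower. The demethylating enzyme gene Tet1 stood at 32.7 ± 4.28 CPM in WT and 20.1 ± 4.98 in CKO and did not pass (edgeR adjusted p = 0.0673). Camera did not call this list (adjusted p = 0.507). Zfp57 lost its call without WT B, Gadd45g without WT A and again without WT B, and Gadd45b without WT A, without WT B and without CKO B. Methylation genes called higher and lower numbered 0 and 1 without WT A, 0 and 0 without WT B, 4 and 2 without CKO A and 1 and 4 without CKO B.

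Neural and Schwann cell markers included the most significant of the named genes. Of 8 tested 5 were higher (Ngfr, Tubb3, S100b, Cnp and Cdh19), 0 lower, and the counts were the same adjusted over the list alone. Ngfr, a neurotrophin receptor, was at 1.14 ± 0.251 CPM in WT and 38.2 ± 1.18 in CKO (SD, n = 2), 33.1-fold higher (edgeR adjusted p = 6.58e-05), and the tubulin gene Tubb3 was 9.85-fold higher. S100b and Cnp were 1.73-fold and 1.66-fold higher, and both lost their calls without WT A and without WT B. The preset correlation called the list (adjusted p = 0.000132), an estimated correlation did not (adjusted p = 0.437), and its calls numbered 3 without WT A and 2 without WT B.

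Among markers of other cell types, those of epithelial, mesothelial, endothelial and chondrocyte cells gave few calls in edgeR. Calls were 2 of 5 lower for erythroid cells, 6 of 18 higher for immune cells and 5 of 8 higher for neural and Schwann cells. Of 20 alveolar epithelial markers and 8 mesothelial markers none passed in edgeR, over all genes or adjusted over each list alone, and camera called neither list (adjusted p = 0.720 and 0.388). At an unadjusted p under 0.05 there was 1 higher marker in each list, and DESeq2 and limma-voom called 0 in both, while edgeR called 1 epithelial marker higher without WT B. The epithelial median log2 change was -0.12 while the direction of its camera test was up. Without WT A the epithelial list was called lower (adjusted p = 0.0232) and without WT B higher (adjusted p = 0.000537), and the mesothelial list was called higher without WT B (adjusted p = 0.0455). Of 18 endothelial markers Plvap was higher (1.96-fold) and Erg lower (1.64-fold), with the same counts adjusted over the list alone, and camera did not call the list (adjusted p = 0.366), except without CKO B (adjusted p = 0.00579). The lower endothelial markers numbered 0 without WT A, 0 without WT B and 2 without CKO A. Of 5 erythroid markers the near-identical globin genes Hba-a1 (2.95-fold) and Hba-a2 (2.83-fold) were lower and 5 were lower when adjusted over the list alone. None of 9 chondrocyte markers passed in edgeR or adjusted over the list alone, 2 were lower at an unadjusted p under 0.05, DESeq2 called 1 lower, limma-voom 0, and edgeR without WT B 3. Col2a1, a cartilage collagen gene, stood at 262 CPM in WT A, 58.3 in WT B, 36.1 in CKO A and 38.2 in CKO B. The preset correlation called the erythroid and chondrocyte lists lower (adjusted p = 0.000660 and 0.0209), an estimated correlation neither (adjusted p = 0.518 and 0.878). The chondrocyte call was lost without WT A and without CKO A (adjusted p = 0.305 in both), and the erythroid calls numbered 1 without WT A, 0 without WT B, 4 without CKO A and 0 without CKO B.

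**Figure D3:**
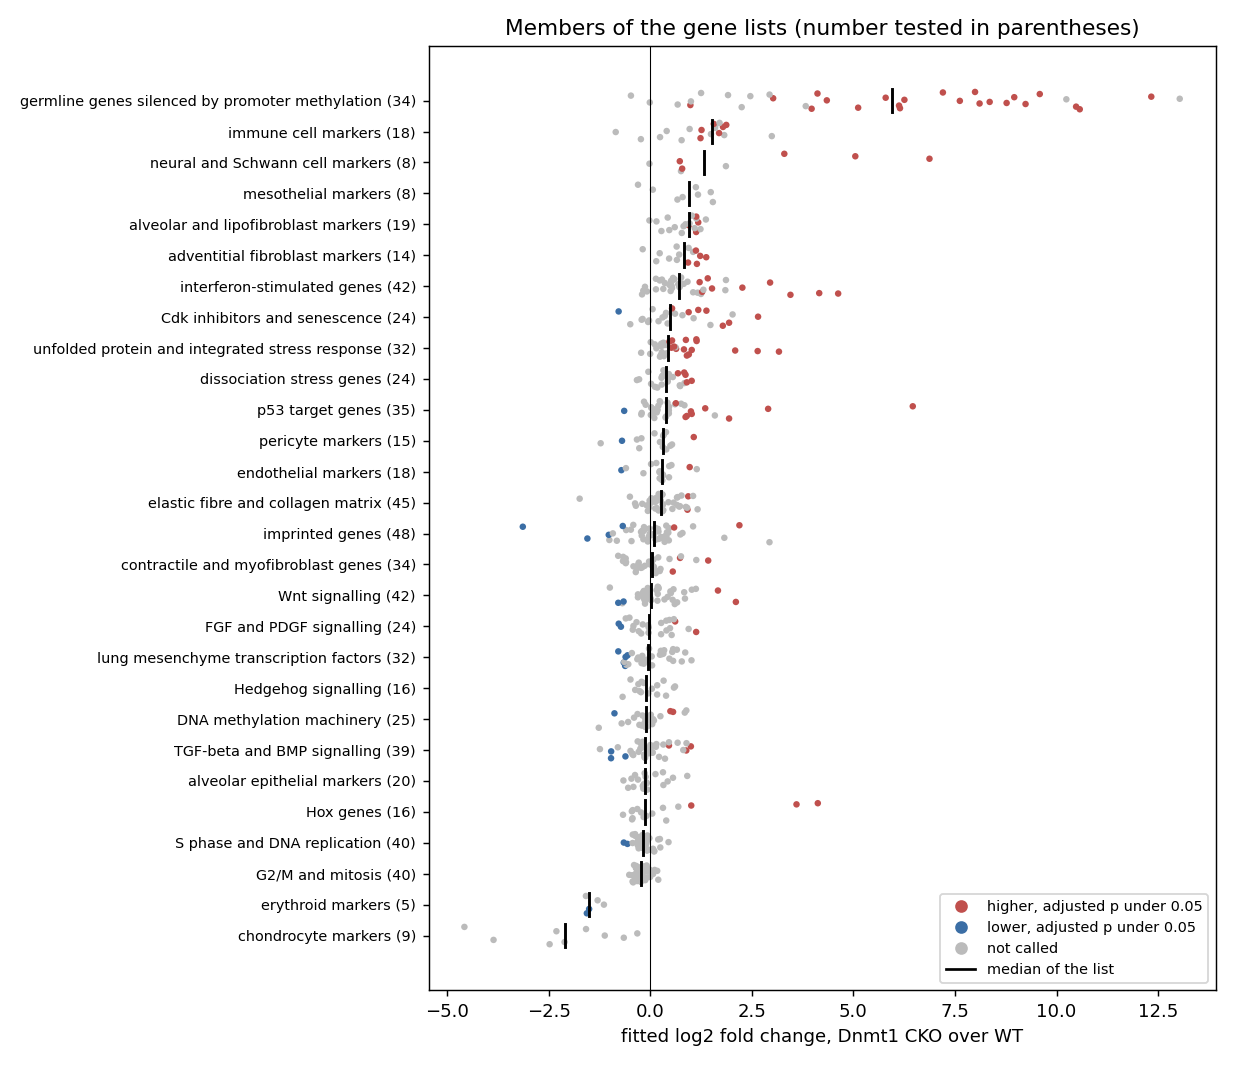
Fitted log2 fold change of CKO over WT for the tested members of each gene list except the sex-linked list, 1 point per gene. The list median is a black bar. Germline genes reach furthest to the right with 22 of 34 called higher, and no G2/M gene of 40 is called.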

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

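The tests in this part were chosen after the result was seen, except the test of X-linked against autosomal genes. A signal outside the tested genes stood out, with 2494 Ddx3y reads in CKO A against 0 in both WT libraries and in CKO B. The same library held Xist at 164 CPM, which is 19.3% of the level of WT A, 24.5% of WT B and 15.2% of CKO B.

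Y-linked reads mark male cells in CKO A, and Xist is normally a female transcript. Silencing of the single X chromosome in CKO A could not be decided. The median log2 ratio of CKO A to CKO B was 0.047 higher for 471 X-linked genes than for autosomal genes. X-linked genes as a set therefore showed no loss in CKO A relative to CKO B. The 95% permutation interval of this difference, 0.014 to 0.082, covers the spread between genes and not between animals. CKO B also differs from CKO A in Y-linked reads and in the level of Dnmt1. Cells of the 3 sequenced libraries without Y-linked reads cannot be told apart as a source. Of 11274 to 11642 autosomal genes of 50 or more reads, 12 for WT A, 18 for WT B and 2 for CKO B lay lower in CKO A than the Xist share allows (95% limits adjusted over these genes), but the limits cover counting error and not the spread between samples of cells. Cells of another female animal, at a share near 0.152 of the Xist level in CKO B, remain possible with no profile to test them against, and so does Xist expressed in male cells without a loss of X-linked RNA, a hypothesis that was not tested.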

How the results depend on the processing

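No paired analysis was possible because the count columns carry no replicate number, and of the numbers that open their names 1 stands before WT A alone and 1 before WT B, CKO A and CKO B. The fit without WT A is the comparison within the shared number, with 603 changed genes. The alternative on deposited RPKM values for Dnmt1 was not run, since those columns were not used, and the one on pseudocounts did not apply to counts. Removal of the length trend, robust estimation switched off, autosomal genes alone and every alternative for the direction by expression level were chosen after seeing the data. In fits without a library the lone sample of a genotype is assumed to vary like the pair of the other. The fit without CKO B sets CKO A, the library with Y-linked reads, against WT libraries without such reads.

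The count of changed genes depended on the threshold, the filter and the libraries. Without a filter on low counts 2459 genes changed (1543 higher and 916 lower), at an adjusted p under 0.01 there were 241 (199 and 42), and under glmTreat 297 (262 and 35). The lower counts follow from the stricter criteria by construction, and the cause of the rise without a filter was not tested. Leaving out a library gave 339 to 1842 changed genes, 248 to 1289 higher and 91 to 553 lower. No alternative called a gene opposite to the fit reported. With the length trend removed 681 genes were higher and 535 lower.

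The odds ratio of direction between the lowest and highest expression quartile ran from 0.442 without WT A to 12.02 in the leave-one-out fits. In the others it ran from 3.01 to 32.7. Quartiles were formed anew over the genes tested in each fit, and the cause of the low value without WT A was not tested. No filter gave no value, as the lowest quartile then held no called gene. The log2 change of Dnmt1 ran from -2.11 to -0.72 in the leave-one-out fits (adjusted p from 3.8e-05 to 0.769), called without CKO A and without CKO B, and from -1.41 to -1.18 in the others without being called. Of the 29 lists 15 were called with the preset correlation, 0 with an estimated correlation (smallest adjusted p = 0.437, 0 at an unadjusted p under 0.05) and 0 with fry (smallest adjusted p = 0.0618), and 14 to 16 in the leave-one-out fits.

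Of the 99 named genes that were called, 63 were still called without WT A, 54 without WT B, 96 without CKO A and 83 without CKO B, and 92 to 99 under the alternatives that kept all libraries. No called gene among those named changed sign. With 2 libraries per genotype the simulated recovery of 2-fold changes was 60%, so changes of that size can be missed.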

Other observations

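The gene families below and the tests of CKO A against CKO B were chosen after the values were seen, except the comparison of interferon-stimulated genes with the strongest rises and the count over splits. Among the families looked up, tested members of 2 gene families on the X chromosome rose. All 9 tested Rhox homeobox genes and all 7 tested Xlr genes were higher in CKO (edgeR, adjusted p under 0.05). Their median fitted log2 changes were 8.07 and 5.92, and near-identical copies within both families can share reads. Copies near 0 reads in WT pass the filter only through their CKO reads. With no filter on low counts 10 of 20 Rhox and 7 of 9 Xlr genes were higher. Rhox calls numbered 7 of 10 tested without WT A, 6 of 10 without WT B, 9 of 9 without CKO A and 7 of 8 without CKO B, and Xlr calls 6 of 7 without CKO B and 7 of 7 in the other fits without a library. Of 5 tested Mage genes edgeR and limma-voom called 0 and DESeq2, which tested 7, 1 higher, with 0 at an unadjusted p under 0.05 in edgeR, 1 higher without CKO A and a median log2 change of -0.19. Of the 237 genes at least 8-fold higher 37 were X-linked (15.6%), against 3.35% of tested genes (Fisher's exact test, odds ratio 5.67, p = 4.26e-15), although neighbouring copies are not independent. Of all tested genes 4.85% were higher and 2.75% lower. Gamma protocadherins gave 4 higher and 0 lower of 21 tested (0 higher without WT B and 8 without CKO A), beta protocadherins 1 higher of 21 (0 without WT B, 0 without CKO B, 3 without CKO A and 0 in limma-voom). Of 3 alpha protocadherins edgeR called 0, as did DESeq2 and limma-voom, and 1 was higher at an unadjusted p under 0.05. Genes with Zfp names gave 4 higher and 19 lower of 349, 2 and 4 without WT A, 0 and 3 without WT B, 10 and 19 without CKO A and 1 and 18 without CKO B. Other families looked up gave 5 higher of 15 with Tex names (2 without WT B), 2 of 9 with Hist names (0 without WT A, 0 without WT B and 1 without CKO B), 2 of 4 ribosomal protein paralogs, 1 of 2 Serpinb1 genes and 1 of 2 Gstp genes (2 without CKO A). None of these families had a lower member with all libraries, though 1 Hist gene was lower without CKO A, and of 40 Slc25 genes 2 were higher (1 without WT A, WT B or CKO B in turn and 4 without CKO A) and 2 lower.

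The imprinted RNA gene H19 stood at 124 CPM in WT A, 54.1 in WT B, 513 in CKO A and 850 in CKO B, and did not pass (log2 difference 2.94, edgeR adjusted p = 0.0803). By gene length, the shortest quartile of tested genes held 304 higher and 74 lower calls and the longest 86 and 178. WT B held 8353 reads of the satellite-like gene Gm10800 against 5 in WT A, 101 in CKO A and 364 in CKO B. Within 10 Mb of Dnmt1 10 of 115 tested genes were called (8.70%), against 7.60% elsewhere (Fisher's exact test, p = 0.597).

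Rises were smaller in CKO A than in CKO B. Of the 237 genes called at least 8-fold higher 223 were lower in CKO A, with a median ratio of CKO A to CKO B of 0.524 (quartiles 0.426 and 0.656). A single factor for depth or scaling is argued against, as the ratio of unscaled reads in these genes was 0.556 times that of 3344 uncalled genes of like mean expression (quartiles 0.452 and 0.697). A smaller recombined share of cells in CKO A may account for the rises, since the losses of Dnmt1 stood in a ratio of 0.515. For the falls it could not be decided. In 220 genes at least 2-fold lower the CKO A change was in the median 1.06 times the CKO B change (quartiles 0.804 and 1.22). In the 153 of them whose WT levels lay within 1.5-fold it was 1.03 times (0.781 and 1.23). In 344 genes 2- to 8-fold higher, chosen on the same fit, it was 0.557 times (0.384 and 0.758). The falls were chosen on the fit over both CKO libraries, which tends to leave out genes that stayed high in CKO A. A fall is limited by the WT level and a rise is not, so the rises do not measure that effect. The same falls gave a median WT share of -0.0582 (quartiles -0.215 and 0.196), which because of that choice cannot decide on admixed WT cells. Cells of the sequenced WT libraries mixed into CKO A are argued against by Xist alone at the share of 0.485 that Dnmt1 would need. Xist in CKO A stood at 19.3% of WT A and 24.5% of WT B. A set of 36 genes chosen for being at least 8-fold lower in CKO B decides neither explanation. Its median share was 15.8%, with quartiles of 1.75% and 87.8%. Y-linked reads were found in CKO A alone, so sex was unbalanced between the genotypes. Whether sex contributes to these ratios was not tested.

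In CKO 9 of 42 interferon-stimulated genes and 6 of 18 immune cell markers were higher. Immune cells as a source cannot be told apart from the sorted cells, although sorting for Pdgfrb-GFP should remove them. The median log2 ratio of CKO A to CKO B differed by -0.50 between the 9 called interferon-stimulated genes (median ratio 0.767) and the 6 called immune markers (median ratio 1.10), a difference between single libraries that immune cells with unlike interferon responses could also give. A rise in the same cells as the strongest rises cannot be told apart from this either, since the ratio of 0.767 lies above the quartiles of those genes (0.426 and 0.656) while its own quartiles of 0.558 and 0.811 overlap them.

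Among the 3 ways to split the 4 libraries into pairs, 1 called as many genes as the genotypes, the genotype split itself, with 1157 genes against at most 3 in the others. These splits are too few for a share under 0.05.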
